A study of Mus musculus with 4 samples.

How the data were processed

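Total RNA of 4 samples of immortalised mouse embryonic fibroblasts with loxP-flanked Ada3 was measured on Affymetrix whole-genome mouse arrays, 2 after infection with control adenovirus and 2 after infection with Cre adenovirus, 3 days after infection, per the labels. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited values are log2 RMA values per probe set, 1 column per array. Affymetrix Expression Console and RMA are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The log2 scale was read from the values, which run from 2.34 to 14.72 with column medians of 5.53 to 5.54. RMA as usually run corrects the background, equalises the distributions of the arrays and summarises each probe set, and a change shared by most genes is removed or reduced by such equalisation. No further normalization was applied for the main results.

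Groups and replicate numbers were taken from the sample titles. Each of the 45101 probe sets was named through the platform annotation table, in which 34945 probe sets have 1 gene, 932 have several, 9160 have none and 64 are controls of the array. Symbols were looked up by gene identifier in a table of RefSeq genes (assembly GRCm38.p6), which held 34754 of these probe sets and changed 0 symbols. Probe sets with several genes or none were not named here. The remaining probe sets measured 18193 genes, of which 9010 had over 1 probe set, and the probe set with the highest mean over all arrays stood for its gene. Genes with a mean at or above the 40th percentile (5.76 on the log2 scale) were tested, 10916 in all. The number of arrays, 2 per group, limits the precision.

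The arrays labelled Cre were compared with the control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with 2 residual and 7.02 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p-values and SEs of single genes in the text are from this fit unless an alternative is named. SEs of medians in the closing part come from the spread over genes or probe sets. For 2 arrays against 2, an exact permutation test of a single gene cannot reach the threshold. The fit was tested on simulated arrays with the spread of the real ones and 10916 genes. It called 84% of 100 genes changed by 0.5 on the log2 scale and 100% of 100 genes changed by 1, with 4 false calls. The simulated genes were independent, followed the fit's own model and carried no replicate or array-wide effect. Far fewer genes were changed than were called in the real data, so the 4 false calls do not measure false calls there.

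The 33 gene lists, the rule for named genes, the test and the processing alternatives were fixed before the data were examined, apart from the poly-A spike scaling and the tests said to be chosen later. The lists, compiled from textbook knowledge, cover SAGA and ATAC subunits, other histone acetyltransferases and deacetylases, DNA replication, mitosis, centromere proteins, G1 regulators, p53 targets, homologous recombination, ribosome biogenesis, ribosomal proteins, cholesterol synthesis, glycolysis and HIF targets, ATF4 targets, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kappaB targets, extracellular matrix, contractile genes, immediate early genes, oxidative phosphorylation, proteasome, NRF2 targets, apoptosis regulators, lysosome and autophagy, retinoid genes and markers of mesenchymal, epithelial, endothelial, macrophage, muscle, adipocyte, neural and bone or cartilage cells. Lists with at least 5 tested members, 31 of the 33, were tested with camera (preset inter-gene correlation of 0.01), adjusted over the lists. Camera called 16 lists, 6 higher and 10 lower. With the correlation estimated from the residuals, 0 lists were called (lowest adjusted p 0.199). The estimate was 0.425 for interferon-stimulated genes, but -0.015, under the preset, for oxidative phosphorylation. For the latter list the unadjusted camera p still went from 7.0e-07 to 0.028. The 0 calls therefore do not by themselves show that correlation between genes undoes the calls. In simulated data the preset version called 5 of 5 lists raised by 0.3 and 0 of 30 unchanged lists, and the version with an estimated correlation called 0 of the 5 raised lists. The simulated genes were independent of each other. The simulation therefore does not show how often the preset version calls unchanged lists of correlated genes.

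The named genes are Tada3, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the largest change past the threshold; further members of a list are named where they illustrate its counts and were chosen after their values were seen. Alternatives were no filter and a filter at the 60th percentile, eBayes without the trend and with robust variances, a second quantile normalization, equal medians, the mean of a gene's probe sets, every probe set tested by itself, the replicate number as a block, each array left out in turn, other thresholds, and for the lists camera on ranks, camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance one way, which has another null than camera. Scaling each array to the mean of its 24 dap, lys, phe and thr spike probe sets was added after the data were seen. With 1 array left out, the lone array of a group is assumed to vary like those of the other group. No coordinates are given, since no genome build is named for the array.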

Results

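The data were 4 Affymetrix whole-genome mouse expression arrays of total RNA from immortalised mouse embryonic fibroblasts in which both copies of Ada3 carry loxP sites. Ada3, listed under its gene symbol Tada3, encodes a subunit of the SAGA and ATAC complexes, which acetylate histones. Growing, asynchronous cells received either a control adenovirus or an adenovirus that carries the Cre recombinase, which removes DNA between loxP sites, and RNA was collected 3 days later. Each group held 2 arrays that the labels call biological replicates. The question was which transcripts changed when Ada3 was deleted. The labels do not say how the replicate cultures were kept apart, so p-values measure only the spread between these arrays, and 2 arrays per group limit the precision. No array analysed here came from Cre-infected cells without loxP sites, so changes brought by Cre or by its virus and changes brought by the deletion fall into 1 comparison. Across all 45101 probe sets, the arrays of a group correlated at r = 0.997 (control) and 0.998 (Cre), and arrays of different groups at 0.993 to 0.994.

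Tada3 was higher, not lower, in the arrays labelled Cre. Its brighter probe set read 7.86 and 7.88 on the log2 scale in the control arrays and 8.36 and 8.41 in the arrays labelled Cre, a difference of 0.51 (SE 0.058, n = 2 per group, limma adjusted p = 0.00015). A second Tada3 probe set, which lay below the brightness filter, averaged 4.78 in the control arrays and 4.71 in the arrays labelled Cre. The sources used here do not give the position of either probe set relative to the deleted part of the gene, and a probe set outside that part does not check the labels. A fall of Tada3 was not seen, and its reading does not check the labels. The groups are therefore called the control arrays and the arrays labelled Cre, and each direction below rests on the labels. The rise of Tada3 was 0.22 with the mean of its probe sets (adjusted p = 0.0465), and it lost its call when arrays were scaled to the poly-A spikes (0.28, adjusted p = 0.0558, the highest over its alternatives).

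Of 10916 genes tested, 5162 (47.3%) differed between the groups, 3183 higher and 1979 lower in the arrays labelled Cre. Most differences were small, with 4522 of the called genes changed by less than 1.5-fold and a median size of 0.30 on the log2 scale among called genes. At least 2-fold changes were seen for 157 genes, 131 higher and 26 lower. In 74.1% of tested genes both arrays of one group lay outside both arrays of the other, where chance gives 33.3% for 2 against 2. The split between higher and lower depended on the scaling. With 61.7% of calls higher in the deposited values, setting the arrays to equal medians and a second quantile normalization each gave 49.2% higher. Scaling to the dap, lys, phe and thr spikes, transcripts added to the RNA before labelling, gave 12.9% higher, an alternative chosen after the spikes were seen to read 0.24 higher in the arrays labelled Cre. That scaling moved the median change of the tested genes from 0.04 to -0.20. Probe sets for 18S ribosomal RNA averaged 11.06 ± 0.51 (SD, n = 2) in the control arrays and 9.24 ± 0.027 in the arrays labelled Cre. The 3' minus 5' difference, a measure of RNA integrity, averaged 0.25 and 0.28 for actin and 1.46 and 1.75 for pyruvate carboxylase in the control arrays and the arrays labelled Cre.

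**Figure D1:**
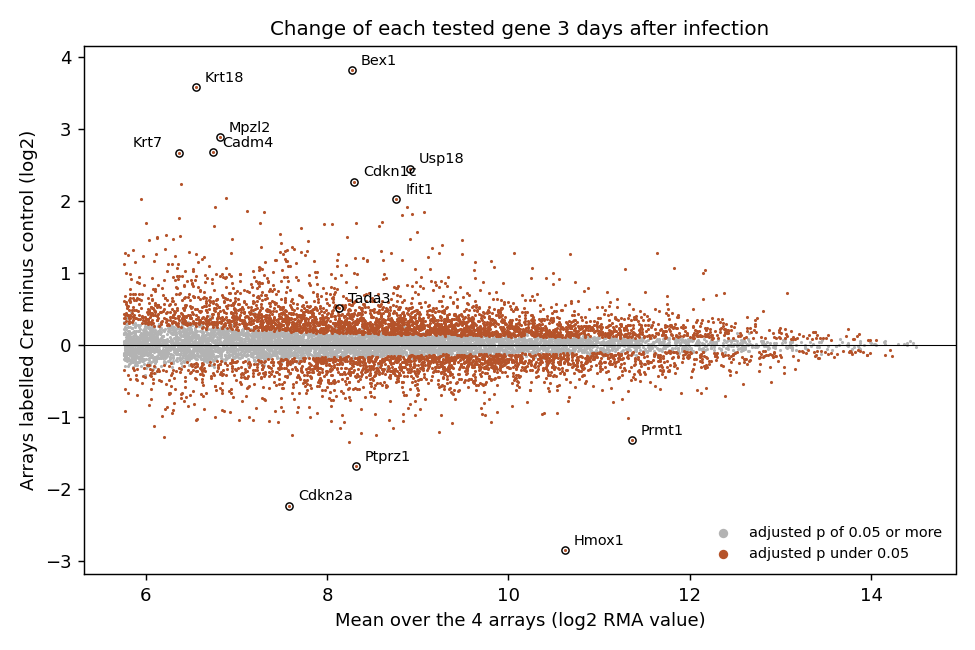
Each point is 1 of the 10916 tested genes, with its mean over the 4 arrays (log2) on the horizontal axis and the difference of the arrays labelled Cre from the control arrays (log2) on the vertical axis, and genes with an adjusted p under 0.05 in the darker colour. Bex1 lies highest at 3.81 and Hmox1 lowest at -2.85, and scaling to the poly-A spikes would lower every point by 0.24.

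Bex1 rose from 6.37 ± 0.23 (SD, n = 2) to 10.18 ± 0.034 on the log2 scale, 14.1-fold. Krt18 and Krt7, keratins of simple epithelia, rose to 8.34 and 7.70, with measured differences of 3.57 and 2.67, and the cell adhesion molecule genes Mpzl2 and Cadm4 to 8.26 and 8.08, with measured differences of 2.88 and 2.67. The control means of Krt18, Krt7, Mpzl2, Cadm4, Oasl2 and Prom1 (4.77 to 5.41) lay below the filter level of 5.76 and are not distinguished from background here, so the sizes and the order of these rises are not exact. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, rose by 2.27 (SE 0.081), from 7.16 to 9.43. The interferon-induced genes Usp18, Oasl2 and Ifit1 rose by 2.44, 2.23 and 2.02. Eprn (2.03), Prom1 (2.03) and Lyz1 (1.91) completed the 12 genes with the largest measured rises. Lyz1 and Lyz2 are near-identical lysozyme genes, so the 2 are not told apart with certainty here.

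Hmox1, the haem-degrading oxygenase, had the largest measured fall, by 2.85 on the log2 scale (SE 0.54, adjusted p = 0.00235), from 12.04 ± 0.059 to 9.20 ± 1.6 (SD, n = 2). Its arrays labelled Cre lay far apart, at 8.06 and 10.34. Without Cre replicate 1 the change of Hmox1 was -1.71, a smaller fall than that of Cdkn2a (-1.79), so its first rank rests on that array. Cdkn2a, whose locus encodes the cell cycle inhibitors p16 and p19, fell by 2.23 (SE 0.22), from 8.69 to 6.03 and 6.90 in the arrays labelled Cre. Ptprz1, a receptor-type tyrosine phosphatase, fell by 1.69 (SE 0.073) and Mex3b, an RNA-binding protein gene, by 1.35. Prmt1, the main arginine methyltransferase of type I, fell by 1.32, or -0.84 without Cre replicate 1. Fam171a2 (-1.27), Ptk7 (-1.25), 3110039M20Rik (-1.24), Zc3h7b (-1.23), Adgra2 (-1.20), Setd5 (-1.15) and Dok1 (-1.15) made up the other largest measured falls, Fam171a2 ending below the filter level at 5.57, and Setd5 stood at -0.64 without Cre replicate 1. A second probe set above the filter did not follow for Zc3h7b (0.02) or Setd5 (0.13). With robust variances, which do not pull unusually variable genes towards the others, the calls of Hmox1, Cdkn2a, Prmt1, Ptk7, Zc3h7b, Adgra2, Setd5 and Usp18 ended, as did 4 of the genes named further on (Ddit4, Atf5, Pcolce and Lyz2), with adjusted p of 0.0507 to 0.215 over these 12 genes, the highest value over their alternatives also being 0.215.

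**Figure D2:**
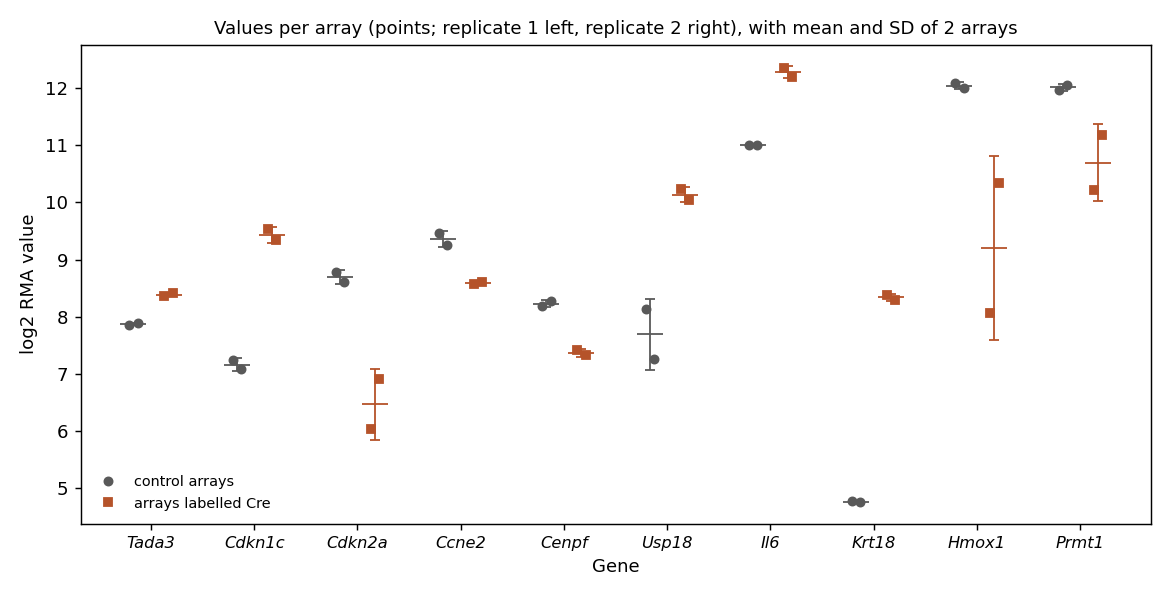
Log2 RMA values of 10 named genes in each of the 4 arrays, with circles for control arrays, squares for arrays labelled Cre, a horizontal bar for each group's mean and whiskers for its SD (n = 2). Tada3 lies higher in both arrays labelled Cre, and Hmox1 and Prmt1 differ between the arrays labelled Cre (8.06 and 10.34 for Hmox1, 10.22 and 11.17 for Prmt1).

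Genes of the cell division cycle fell together. Of 43 tested genes of DNA replication and the G1/S transition, 40 fell, 0 rose and 3 did not pass, with 40 falls adjusted over the list alone. Among them Ccne2 (cyclin E2) changed by -0.78, Pola1 (DNA polymerase alpha) by -0.77, Cdc6 (origin licensing) by -0.74 and the helicase subunit Mcm7 by -0.59. The list's median was -0.36 and camera, which compares a list with all other genes, placed it lower (adjusted p = 8.8e-18, but adjusted p = 0.199 with an estimated correlation). Of 52 G2/M and mitotic genes 49 fell and 1 rose (50 and 1 adjusted over the list alone), with a median of -0.45 (adjusted p = 4.23e-21, and adjusted p = 0.199 with an estimated correlation). Fbxo5, an inhibitor of the anaphase-promoting complex, changed by -0.88, Cenpf by -0.86, Melk by -0.71 and the proliferation marker Mki67 by -0.62, while securin (Pttg1) rose by 0.44. Scaled to the poly-A spikes, 42 replication genes fell and 0 rose, and 51 mitotic genes fell and 0 rose.

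Centromere proteins and the genes of homologous recombination fell as well. Among 22 constitutive centromere and CENP-A loading genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), the median being -0.25 (camera adjusted p = 2.98e-06, and adjusted p = 0.199 with an estimated correlation). Cenpu changed by -0.67, Cenph by -0.52 and Cenpa, the centromeric histone variant, by -0.37, whereas the gene of the satellite-binding protein Cenpb rose by 0.28. Of 24 homologous recombination, Fanconi anaemia and replication checkpoint genes, 19 fell and 0 rose (also 19 adjusted over the list alone), with Rad51ap1 at -0.61, Clspn at -0.60, Rad54l at -0.57 and Brca1 at -0.45. Their median was -0.37 (adjusted p = 4.46e-09, and adjusted p = 0.199 with an estimated correlation). Without control replicate 1, 0 centromere genes rose and 13 fell, and without Cre replicate 1, 0 rose and 11 fell. With spike scaling 19 centromere and 22 recombination genes fell and 0 rose.

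Regulators of G1 moved both ways. Of 25 tested G1 cyclins, kinases, inhibitors and regulators, 4 rose, 11 fell and 10 did not pass, the same counts as adjusted over the list alone, and 1 rose and 13 fell with spike scaling. Only 2 rose without control replicate 1 (9 fell), control replicate 2 (9 fell) or Cre replicate 1 (10 fell). Beside the rise of Cdkn1c and the fall of Cdkn2a, Cdkn2c (p18) changed by -0.60, Myc by -0.47, the ubiquitin ligase subunit Skp2 by -0.46 and Cdkn1b (p27) by -0.38. Cdkn1a (p21) differed by 0.07 and did not pass (adjusted p = 0.138). The list's median was -0.03 (-0.06 without control replicate 1, -0.01 without control replicate 2, -0.09 without Cre replicate 1 and -0.07 without Cre replicate 2) and camera placed it lower (adjusted p = 0.0334, but adjusted p = 0.245 with an estimated correlation), a call that also ended with the stricter filter, a second quantile normalization or the mean of probe sets. Among 30 p53 target genes 6 rose and 9 fell, also adjusted over the list alone, with Rrm2b (ribonucleotide reductase) at 0.41, Ddit4l at -0.43 and Pmaip1 (NOXA) at -0.40, and the list was not called (camera adjusted p = 0.156). Of 27 apoptosis regulators 9 rose and 6 fell (10 and 6 adjusted over the list alone), among them the caspases Casp12 (0.71) and Casp4 (0.70), Bid (0.48) and Bok (-0.44), and camera did not call the list (adjusted p = 0.917). After scaling to the spikes, 0 of the p53 targets rose and 16 fell, and 2 apoptosis regulators rose and 10 fell.

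Interferon-stimulated genes showed the broadest rise. Of 34 tested members 31 rose, 0 fell and 3 did not pass (32 rises adjusted over the list alone), with a median of 1.11. Usp18, a brake on interferon receptor signalling, rose from 7.69 ± 0.62 to 10.14 ± 0.13 (SD, n = 2), and Xaf1 (1.82), Rtp4 (1.80), Stat2 (1.12, from a control mean of 5.69 below the filter level), Irf7 (0.96) and the class I histocompatibility gene H2-K1 (0.64) rose as well. Irf1 (0.16), Ifit2 (0.03) and Ccl5 (0.02) did not pass. The list stood higher by camera (adjusted p = 1.32e-12, but adjusted p = 0.295 with an estimated correlation, which was 0.425 for these genes). Its members also differed between the control arrays, whose means over the list were 7.99 and 7.68, against 8.94 and 8.87 in the arrays labelled Cre. The poly-A spike scaling left 26 members higher and 0 lower.

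Inflammatory genes rose with them. Among 29 NF-kappaB targets, cytokines and secreted factors of senescent cells, 22 rose, 4 fell and 3 did not pass, the same as adjusted over the list alone. The cytokine Il6 rose by 1.27 (SE 0.047), the iron-chelating lipocalin Lcn2 by 1.26, the growth factor binding protein Igfbp3 by 1.21 and the adhesion molecule Icam1 by 1.17, while Mmp9 (-0.45), Igfbp5 (-0.35), Vcam1 (-0.26) and Cxcl12 (-0.18) were lower. With a median of 0.64 the list was called higher (camera adjusted p = 9.1e-07, but adjusted p = 0.219 with an estimated correlation), and 15 members rose and 5 fell after scaling to the spikes. Of 7 tested macrophage and leukocyte markers, 2 rose and 1 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.917). These counts were 2 and 2 with equal medians or a second quantile normalization, and 2 and 3 with spike scaling. Lyz2 rose by 1.51 (0.98 without control replicate 1), from a control mean of 5.62 below the filter level, and Csf1r by 1.07, although another Csf1r probe set changed by 0.00, and Laptm5 was lower by -0.29 (no longer called without control replicate 1, at -0.20, or without Cre replicate 1, at -0.23). The pan-leukocyte gene Ptprc, below the filter, read 4.27 in the control arrays and 3.74 in the arrays labelled Cre, and the macrophage genes Adgre1 (4.86 and 4.75) and C1qa (4.95 and 4.69) were also dim.

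**Figure D3:**
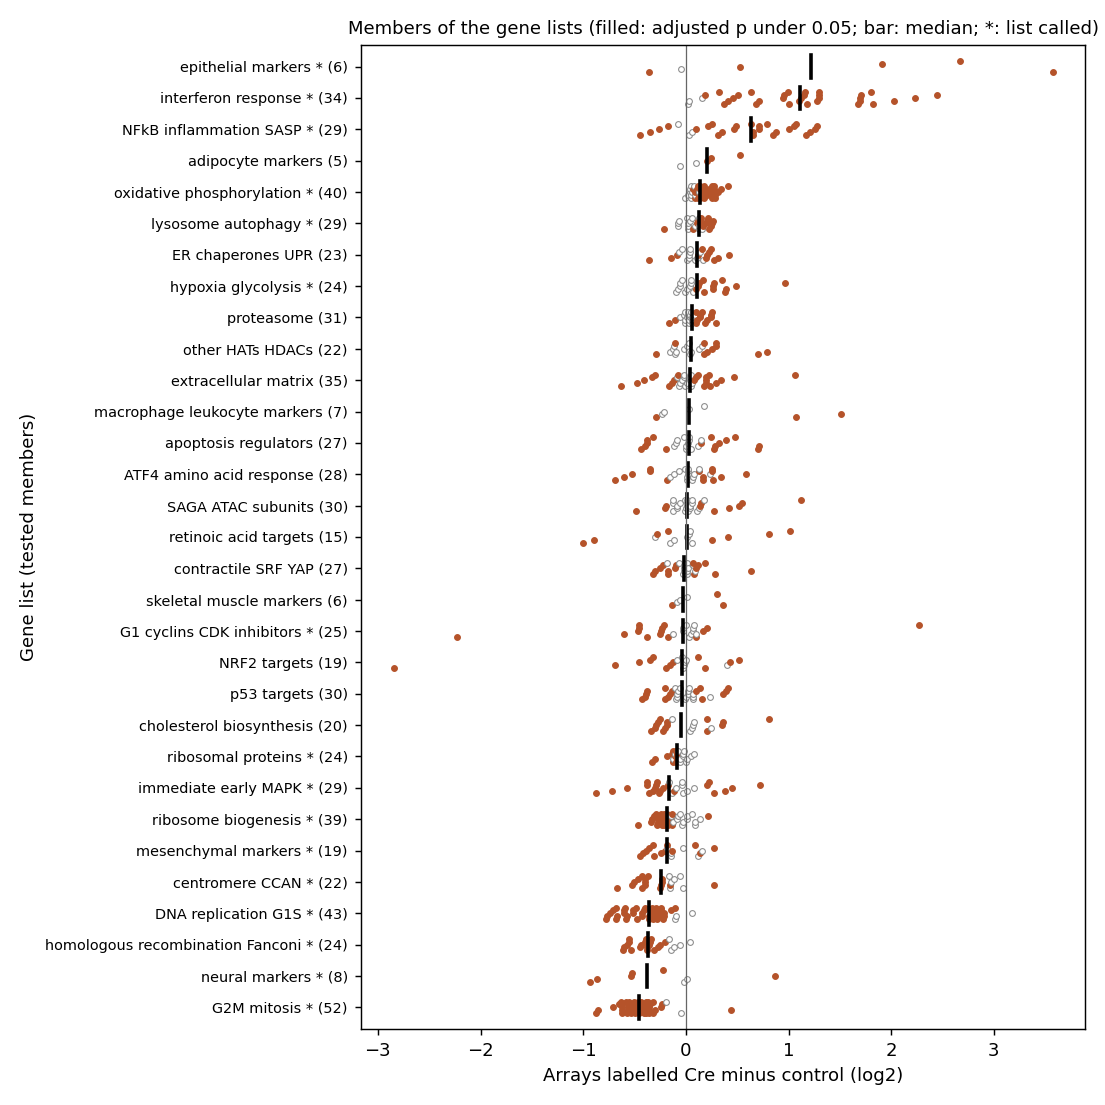
Log2 difference of the arrays labelled Cre from the control arrays for every tested member of 31 gene lists, ordered by the list median (black bar), with filled points for members past the test, the number of tested members in brackets and an asterisk for each of the 16 lists called by camera. Mitotic genes lie lowest (median -0.45) and interferon-stimulated genes among the highest (1.11), and scaling to the poly-A spikes lowers every point by 0.24, which puts the medians of oxidative phosphorylation, lysosome and glycolysis genes below 0.

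Genes that make ribosomes were lower. Of 39 nucleolar ribosome biogenesis genes 25 fell and 1 rose (26 and 1 adjusted over the list alone), including Gar1 (-0.47), Wdr12 (-0.34), Nop58 (-0.33) and nucleolin (Ncl, -0.27), and the list was called lower with a median of -0.18 (adjusted p = 2.87e-07, but adjusted p = 0.219 with an estimated correlation). Of 24 cytosolic ribosomal protein genes 12 fell and 0 rose (13 adjusted over the list alone), with Rpl8 at -0.33 and Rpl7 at -0.18 (1 rise and 9 falls without control replicate 2) and a median of -0.09 (adjusted p = 7.63e-05, but adjusted p = 0.219 with an estimated correlation). The 18S ribosomal RNA control probe sets differed by -1.81, with 11.41 and 10.70 in the control arrays and 9.26 and 9.23 in the arrays labelled Cre. What sets this reading was not tested, and it is not used here as evidence about ribosomes. With spike scaling 31 ribosome biogenesis and 21 ribosomal protein genes fell and 0 rose.

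Small rises ran through mitochondrial, glycolytic and lysosomal genes. Of 40 nuclear-encoded respiratory chain and ATP synthase subunits, 29 rose and 0 fell (30 rises adjusted over the list alone), with Uqcrc1 at 0.41, Ndufb6 at 0.34 and Cox8a at 0.31, but 0 rose and 1 fell when arrays were scaled to the spikes. The list's median was 0.14 (camera adjusted p = 2.98e-06, adjusted p = 0.199 with an estimated correlation, and 0.177 after spike scaling). Of 24 glycolysis and HIF target genes 13 rose and 0 fell, the same adjusted over the list alone, against 2 rises and 5 falls after spike scaling. Among the rises were Ndrg1 (0.97), Ero1a (0.49) and the glucose transporter Slc2a1 (0.27). Over the probe sets above the filter, changes ran from 0.09 to 0.49 for Ero1a and from 0.50 to 1.24 for Ndrg1. The median of the glycolysis and HIF list was 0.11, or 0.095 without control replicate 1 and 0.098 without Cre replicate 2. That list's call was marginal (adjusted p = 0.0336, adjusted p = 0.245 with an estimated correlation) and ended without control replicate 1 (0.0551) or Cre replicate 1 (0.0576), with equal medians, with the stricter filter, with the mean of probe sets or with spike scaling, its adjusted p ranging from 0.00117 to 0.273 over the alternatives. Of 29 lysosome and autophagy genes 14 rose and 1 fell, also adjusted over the list alone, among them the cathepsin Ctsz (0.27) and the hexosaminidase Hexa (0.25), with counts of 10 and 0 without control replicate 1, 12 and 0 without control replicate 2, 11 and 0 without Cre replicate 1, and 11 and 2 without Cre replicate 2. Camera gave an adjusted p of 0.0226 (adjusted p = 0.245 with an estimated correlation, 0.0812 with equal medians). With spike scaling 0 rose and 4 fell, and the call ended with a camera adjusted p of 0.717, the highest over its alternatives.

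Other metabolic and stress lists were not called by camera in the deposited values. Among 31 proteasome subunits 12 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0899), with Psmc4 at 0.29 and Psmb5 at 0.26, against 0 rises and 6 falls after spike scaling. The proteasome counts were 8 and 0 without control replicate 1, 8 and 1 without control replicate 2, 10 and 1 without Cre replicate 1, and 8 and 1 without Cre replicate 2. Camera called the proteasome list higher without the filter and after a second quantile normalization. Among 23 endoplasmic reticulum chaperone and unfolded protein response genes 9 rose and 3 fell (10 and 3 adjusted over the list alone, 7 and 1 without control replicate 1), with Sdf2l1 at 0.42 and Pdia3 at -0.36 (adjusted p = 0.264), against 0 rises and 5 falls after spike scaling. Of 28 ATF4 target genes 8 rose and 6 fell, also adjusted over the list alone, with the serine synthesis enzyme Psph at 0.59, Ddit4 at -0.60 and Atf5 at -0.53, or -0.39 and -0.29 without Cre replicate 1 for the latter 2 genes. Camera gave that list an adjusted p of 0.915, with a negative direction and mean (-0.0079) beside a positive median, and 7 rose and 9 fell with equal medians and 1 rose and 10 fell with spike scaling. Of 20 cholesterol synthesis genes 5 rose and 9 fell (6 and 9 adjusted over the list alone, 3 and 9 without control replicate 1, 3 and 8 without Cre replicate 2), with the sterol reductase Tm7sf2 at 0.81 and Msmo1 at -0.34, and the negative median (-0.05, or -0.02 without control replicate 2) and direction of the test differed in sign from the mean of 0.0021 (adjusted p = 0.217). With spike scaling 1 cholesterol gene rose and 10 fell. Of 19 NRF2 antioxidant response genes 4 rose and 8 fell (5 and 8 adjusted over the list alone), with Hmox1 and Nqo1 (-0.45) lower and Gstm1 (0.52) higher, and the list did not pass (adjusted p = 0.0831) except without Cre replicate 1 (0.0212) or with spike scaling (0.000617), with a range of 0.000617 to 0.295 over the alternatives, and 1 member rose and 13 fell with spike scaling. Fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 7 lists that camera did not call, those of NRF2 targets, the proteasome, endoplasmic reticulum chaperones, apoptosis regulators, SAGA and ATAC subunits, other histone acetyltransferases and deacetylases, and adipocyte markers.

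Immediate early genes fell more often than they rose. Of 29 immediate early and ERK feedback genes 15 fell and 6 rose (16 and 6 adjusted over the list alone), with Jun at -0.87, Klf4 at -0.72 and Klf6 at -0.57 among the falls and Maff (0.72), Fos (0.45) and the phosphatase Dusp1 (0.38) among the rises. The median was -0.16 (camera adjusted p = 0.00389, but adjusted p = 0.219 with an estimated correlation), and 1 rose and 20 fell with spike scaling. Extracellular matrix genes split, with 13 of 35 higher and 9 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.917, with a negative test direction beside a positive median and mean). The metalloproteinase inhibitor Timp3 rose by 1.06 and the procollagen processing enhancer Pcolce by 0.47, while Col6a3 changed by -0.63 and periostin (Postn) by -0.48. With equal medians 9 of these matrix genes rose and 10 fell, and with spike scaling 1 rose and 16 fell. Of 27 contractile, SRF and YAP target genes 7 rose and 8 fell, also adjusted over the list alone, with Tgfbi at 0.63 and the integrin gene Itga5 at -0.32 (adjusted p = 0.264). These counts were 3 and 10 with equal medians, 1 and 14 with spike scaling, 4 and 5 without control replicate 1, 3 and 7 without control replicate 2, and 3 and 6 both without Cre replicate 1 and without Cre replicate 2. Retinoid genes likewise moved both ways, with 4 of 15 higher and 4 lower, also adjusted over the list alone. The retinoic acid binding protein gene Crabp2 (1.02) and the retinol dehydrogenase gene Rdh10 (0.81) rose. Aldh1a1 (-0.90) and Dhrs3 (-1.24 to -0.93 over its alternatives) fell. The list was not called (adjusted p = 0.497, with a positive median of 0.01 beside a negative mean and test direction). That median was -0.01 without control replicate 1, -0.06 without control replicate 2, -0.02 without Cre replicate 1 and -0.04 without Cre replicate 2, and with spike scaling 2 retinoid genes rose and 7 fell.

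Most genes of the complexes that hold Ada3 did not pass the test. Of 30 SAGA and ATAC subunit genes 7 rose, 3 fell and 20 did not pass, the same as adjusted over the list alone, and the list was not called (adjusted p = 0.917). Taf9b rose by 1.12 (from 5.73, just below the filter level), Sf3b5 by 0.55 and Kat2b, one of the catalytic acetyltransferases, by 0.27, and Sf3b3 changed by -0.48. Kat2a, another catalytic subunit gene, differed by -0.09 (adjusted p = 0.215). With equal medians 5 rose and 5 fell, with spike scaling 2 rose and 9 fell, and with the mean of probe sets 2 of 28 rose and 3 fell. Among 22 other histone acetyltransferases and deacetylases 8 rose and 2 fell, also adjusted over the list alone, with Hdac11 at 0.79, Hdac5 at 0.71 and Hat1 at -0.29 (camera adjusted p = 0.75). These counts were 7 and 5 with equal medians, 2 and 7 with spike scaling, 8 and 1 without control replicate 1, 5 and 1 without control replicate 2, and 6 and 1 without Cre replicate 2.

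Markers of the fibroblasts and of other cell types were examined on the same arrays. Of 19 mesenchymal markers 10 fell and 3 rose, also adjusted over the list alone, with Thy1 at -0.45, Snai2 at -0.42, Cd44 at -0.39 and Cdh2 (N-cadherin) at -0.36, a median of -0.18 and a camera adjusted p of 0.00328 (adjusted p = 0.219 with an estimated correlation). Without Cre replicate 1 the mesenchymal median was -0.12, with 1 rise and 10 falls, and with spike scaling 0 rose and 14 fell. Of 6 tested epithelial markers 4 rose and 1 fell, also adjusted over the list alone, and 4 rose and 0 fell without control replicate 2 or without Cre replicate 1. Beside Krt18 and Krt7, the desmosome gene Dsp rose by 1.91 and Krt19 by 0.53, Cldn3 changed by -0.36, and Epcam differed by -0.04 and did not pass. The list was called higher (adjusted p = 0.0186, but adjusted p = 0.245 with an estimated correlation), and the call ended without the filter and on ranks. E-cadherin (Cdh1), below the filter, read 3.11 in the control arrays and 3.16 in the arrays labelled Cre. Among 8 neural markers 5 fell and 1 rose, also adjusted over the list alone, with Stmn2 at -0.93, Gap43 at -0.86, nestin (Nes) at -0.53 and Mbp at 0.86, a median of -0.37 and an adjusted p of 0.00681 (adjusted p = 0.245 with an estimated correlation).

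Muscle, fat, vessel and cartilage markers gave no list called by camera. Of 6 muscle markers 2 rose and 1 fell, also adjusted over the list alone, but 0 rose and 0 fell without Cre replicate 1, and 1 rose and 1 fell without any of the other arrays in turn (camera adjusted p = 0.84, with a positive mean of 0.06 beside a negative test direction and a median of -0.03, or 0.03 without Cre replicate 1 and -0.05 without Cre replicate 2). Mylpf, with a control mean of 5.74 just below the filter level, stood at 0.36 (not called without control replicate 2, at 0.29, or Cre replicate 1, at 0.30), Actc1 at 0.30 (not called without control replicate 1, at 0.20, Cre replicate 1, at 0.34, or Cre replicate 2, at 0.27) and Acta1 at -0.14 (not called without Cre replicate 1, at -0.11). With spike scaling 0 muscle markers rose and 2 fell, and after a second quantile normalization 0 rose and 1 fell. Of 5 adipocyte markers 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.217), with lipoprotein lipase (Lpl) at 0.53 and Scd1 at 0.24 (not called with the mean of its probe sets), and 1 adipocyte marker rose with spike scaling. Only 4 endothelial and 3 bone or cartilage markers passed the filter, too few to test as lists. Of the endothelial markers 2 rose, Egfl7 at 0.37 and Kdr at 0.40 (not called without Cre replicate 2, at 0.31), also adjusted over the list alone, and with spike scaling 0 rose and 1 fell. Of the bone and cartilage markers 2 fell (3 adjusted over the list alone), with the collagen genes Col11a1 at -0.98 and Col2a1 at -0.48.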

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

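The spike readings and probe sets without a gene name lie outside the comparisons of the report, and all tests in this part were chosen only after the results were seen. The P1 cre hybridization spike probe sets read 0.27 higher in the arrays labelled Cre, the dap, lys, phe and thr spikes 0.24 higher, and the bioB, bioC and bioD hybridization spikes -0.05. Of the 1883 tested probe sets among the 9160 with no gene name, 8 were at least 2-fold higher, which drew attention to them, and 6 at least 2-fold lower. Among the 10916 tested genes these counts were 131 and 26, so 2-fold rises were not more frequent among the unnamed probe sets.

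Tada3 read higher in both arrays labelled Cre, for which an exchange of the labels could account, and cells with the Cre virus might then add cre transcripts to the P1 cre reading of the arrays labelled control. The P1 cre reading minus that of the bio spikes was instead 0.32 higher in the arrays labelled Cre (pooled SD 0.134), but the dap, lys, phe and thr spikes, which no virus brings, moved by 0.29 against the bio spikes. These differences were 0.19 and 0.07 without Cre replicate 1 and 0.45 and 0.51 without Cre replicate 2, so the reading leaves this open. A probe set outside the deleted part may also rise or stay level after the deletion, and the second Tada3 probe set, at -0.069, lies below the filter and leaves that open. A biological rise of the remaining transcript was not tested, and these explanations cannot be told apart here.

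Krt18 and Krt7 rose together, and epithelial cells among the fibroblasts are a possible explanation. Of the other epithelial list members on the array, 4 lay above the filter and moved both ways, Dsp (1.91) and Krt19 (0.53) up, Cldn3 (-0.36) down and Epcam at -0.04, with a median change of 0.24 (SE 0.63), which leaves this open. Krt8, the partner of Krt18 in simple epithelia, changed by 0.39, from 5.49 to 5.98 and 5.77 in the arrays labelled Cre, close to the filter level of 5.76, and the remaining members lay below the filter, so these decide nothing. A change within the fibroblasts was not tested, and it cannot be told apart from added epithelial cells here.

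In 19 genes, Hmox1, Cdkn2a, Prmt1, Ptk7, Zc3h7b and Setd5 among them, Cre replicate 1 lay at least 0.5 below Cre replicate 2 while the control arrays differed by under 0.25, and the fall in replicate 2 was a median of 0.456 of that in replicate 1. A weaker response of all genes in replicate 2 is argued against by the other 279 called falls of at least 0.5, whose median ratio was 0.961 (SE 0.017). These 279 leave out the 19 genes by construction, and being called favours genes whose arrays agree, so the ratio holds for those 279 only. The readings may belong to single probe sets, since 9 other probe sets of 7 of these genes showed a median of 0.035 of the fall (SE 0.22), but those of Psap (-0.81) and Arl2bp (-0.87) also read lower, which leaves this open. The design gives no biological difference between the replicates to test.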

How the results depend on the processing

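The poly-A spike scaling was chosen only after the data were seen. It left 4380 calls, 567 higher and 3813 lower, brought Tada3 to 0.28, and reversed Map1lc3a (-0.0084) and Fabp4 (-0.029), because it lowers every change by 0.24. A 2-fold limit left 157 genes (131 higher, 26 lower), with or without the p-value, and testing each of 18715 probe sets by itself gave 6994 calls, 3989 higher and 3005 lower. With an estimated correlation 0 lists were called, while the other camera alternatives called 13 to 16 against 16. Simulated lists of independent genes raised by 0.3 were not recovered by the version with an estimated correlation either. Its 0 calls therefore do not by themselves show that correlation between genes undoes the calls. Leaving out 1 array gave 3876 to 4161 called genes against 5162, and 0.49 to 0.54 for Tada3. With the replicate number as a replicate block 5778 genes were called (3534 higher, 2244 lower), all 5162 among them, and no call of a named gene or list changed. Replicate 1 minus 2 correlated between the groups at r = 0.207 across genes, which are not independent replicates. Between the groups, arrays of the same replicate number correlated at r = 0.9940 and 0.9940, and arrays of different numbers at 0.9934 and 0.9933. The second principal component, the second largest axis of difference between arrays, read 11.4 (control) and 11.5 (Cre) in replicates 1 and -11.5 in both replicates 2. These readings go with an effect shared by arrays of the same number, which the main fit does not model. The labels name no shared day, and 2 pairs do not show its source. Of 1904 values of 139 named genes under the alternatives, 1826 kept direction and call, 76 lost the call (29 with spike scaling, 12 with robust variances) and 2 reversed. For the 31 lists, 451 of 492 values kept the call, 30 lost it (16 with an estimated correlation), 11 gained it (7 by fry, which passed 23 lists but asks whether genes move on balance one way, not whether they differ from other genes) and 0 reversed. Where not stated, the cause was not tested. Genes below 5.76 are not distinguished from background here.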

Other observations

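The genes in this paragraph lie outside the fixed lists and were chosen after their values were seen. Rises included the chaperone clusterin (Clu, 1.65), the interleukin Il18 (1.53), the chemokines Ccl8 (1.36) and Cxcl14 (1.26), Wnt4 (1.41), the protease inhibitor Slpi (1.26) and the glucose transporter Slc2a3 (1.65). The GTPases Iigp1 (1.84) and Irgm2 (1.62) and the guanylate-binding protein Gbp7 (1.28) also rose. Falls included the plasminogen activator gene Plau (-1.04), the Kit ligand gene Kitl (-0.94), matrix Gla protein (Mgp, -1.08), the chemokine receptor Ackr3 (-0.97), the progenitor marker Cd34 (-0.99) and the phosphatidylinositol 3-kinase subunit Pik3r1 (-0.96), all past the limma test.

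Cdkn1c (2.27), Phlda2 (1.46) and Igf2 (0.87), which are imprinted, were all higher in the arrays labelled Cre. The control means of Phlda2 (5.31) and of Nnat (5.44), named further on, lay below the filter level, so the sizes of their changes are not exact. The hypothesis that imprinted genes rose as a class was written down after these 3 were seen and before the others were looked at. The other 24 imprinted genes above the filter had a median change of 0.061 (SE 0.093), with 10 higher and 5 lower, and camera did not place them apart from other genes, which argues against a rise of the class. Peg3 (0.84), Mest (0.84), Nnat (0.78) and Dlk1 (0.64) rose, and Rian (-0.50) and Mirg (-0.30) fell.

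Some genes differed between the replicate numbers in both groups. Malat1, a nuclear long RNA, was higher in replicate 1 than in replicate 2 by 1.12 in the control arrays and by 1.22 in the arrays labelled Cre. Of 17 genes at least 0.7 apart between the control replicates, 16 differed in the same direction in the arrays labelled Cre.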
